A study of Mus musculus with 2 samples.

How the data were processed

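The assay for transposase-accessible chromatin with sequencing (ATAC-seq) cuts open DNA with the Tn5 transposase and sequences the fragments, so that regions of open chromatin collect reads. Per the labels, it was run on granulocyte monocyte progenitors (GMP), the bone marrow cells that give rise to neutrophils and monocytes, from adult male C57BL/6J mice aged 5 to 6 weeks. The 2 samples are biological replicates of 1 group with an input of 50000 cells each, and they carry separate biosample identifiers with the same donor label. How the cells were sorted is not given in the sources used here. The labels name a pair of sequencing instruments for replicate 1 and none for replicate 2.

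Deposited files were lists of accessible regions, without read counts. Per the submitters' file list, the coordinates are in mm10, each replicate has its own lists, and the series has further lists made from the reads of both replicates together. The aligner, the peak caller, their versions and any shift of read ends for Tn5 are not given in the sources used here. Each row of a list carries, as deposited, a fold enrichment (a ratio whose denominator is not given in the sources used here), a p and a q value on a -log10 scale, and the position of its summit. Ranked lists deposited beside them carry a score made from the irreproducible discovery rate (IDR), a measure of how well a row's rank repeats between replicates or between random parts of the reads. Tested on the files, the thresholded lists hold the rows of the ranked lists with a score of at least 540 (-log10 of the IDR of at least 1.30), less 187 rows in replicate 1 and 194 rows in replicate 2. Fold enrichment is the authors' own value for each row, and was used only to describe, rank or filter regions within a list. In the ranked list made between the replicates, 8 columns without names hold values of single replicates and were not used.

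The main list was the series-level conservative list, whose rows were called on the reads of both replicates and passed the IDR threshold between replicate 1 and replicate 2. For values per replicate, each replicate's own thresholded list was used, which rests on random parts of that replicate's reads. Rows overlapping by at least 1 bp were merged into regions, each with the summit and the fold enrichment of its row with the highest fold. Read depth is unknown, because the files give no counts, so no interval or detection limit was computed from depth. A region missing from a list is therefore only one that did not pass its threshold.

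Regions were annotated with GENCODE vM21 on the GRCm38.p6 reference, whose chromosomes are those of mm10. Tests used the 21670 protein-coding genes on the 19 autosomes and X. Promoters were the 1000 bp on either side of an annotated transcription start site (TSS) of a protein-coding gene. Other summits were classed as exon, intron or intergenic, in that order, from the genes of every type in the annotation. The observed overlap between replicates and the annotation classes were compared with 100 random placements, in which a list was rotated by a random offset within each chromosome. The smallest p that 100 placements give is 0.0099 for the overlap (one-sided) and 0.0198 for the classes (two-sided).

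Before the data were examined, 18 gene lists (259 symbols, 258 of them matched), 20 consensus motifs, 11 known enhancer positions, the tests and the processing alternatives were fixed. Promoter shares of lists were tested with a two-sided Fisher's exact test against all other genes. For distal regions, over 1000 bp from every protein-coding TSS and assigned to the gene with the nearest TSS, the median number per gene of a list was set against 10000 random lists of the same size, matched on decile of the gene's territory, with a two-sided permutation p. Both families of p were adjusted by the Benjamini-Hochberg method over the 18 lists, with a threshold of 0.05. Genes are not independent replicates, so these p-values describe these lists of regions. For motifs, the share of summits with a match within 50 bp was divided by the share in windows 500 bp to each side, and a motif was called where the mean log2 ratio over 20 chromosomes lay beyond 2 SD of the chromosome values. The log2 ratios given are those over all summits, with the SD over chromosomes, and for rare motifs they differ from the mean over chromosomes. This SD is the spread of single chromosomes and not the error of the ratio. A motif within the limit can therefore still differ from the flanks. The closing section gives the smaller SE over chromosomes, so its values are not held to this limit. For a known enhancer, a region had to lie within 2000 bp of the stated distance from any TSS of the gene. Where several did, the region with the highest fold was taken, which need not be the closest. The use of 1 summit per region, the definition of territory and the motif threshold were set after the files had been opened and before any result was seen.

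Named genes were fixed as 47 members of the lists, the genes of the enhancer positions, and the nearest genes of the 5 promoter and 5 distal regions with the highest fold that were also in the lists of both replicates. Other genes are named where a list had few members on the side described, or to illustrate a list, and were chosen after their values were seen. They are Id2, Klf4, Zeb2, Fli1, Ly86, F13a1, Hbb-bs, Hbb-bt, Tfrc, Cd3d, Thy1, Cd28, Eomes, Apob, Actn2, Ttn, Blk, Meis1, Syn1, Snap25, Gad2 and Grin1.

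The alternatives left out each replicate in turn, or took the authors' looser lists or the regions with the highest fold. The latter were 37574 of the 75148 regions of the series-level list, and the same share of each replicate's list for the overlap. Others varied the merging of rows, the overlap that counts as shared, the promoter window and the background of gene lists. The assignment of regions to genes, the motif window and background, and the distance tolerance at enhancers were varied too. The overlap, gene list, motif and rank methods were tested on simulated data. With 69.99% of 53685 regions kept in place and the others moved, the overlap method found 70.6% shared. Fisher's test called 100% of lists whose promoters were all set open and 2% of other lists, each of 10 genes. Openness in that simulation did not depend on promoter GC content, so the 2% does not cover lists of unusual GC content. The distal test called 3% of lists whose counts were raised by a fold of 2, 49% at a fold of 4 and 0.5% of others, over 21670 genes, so it detects only large differences. A PU.1 sequence planted in 5% of 73214 windows was found in 5.42% (0.439% in the flanks), and 0 of the other motifs were called. Ranks moved by 7.44 percentile points in a seeded part of 36000 simulated regions came out moved by 8.36 (SE 0.51), and an unchanged set by 0.42 (SE 0.40).

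For the closing section, chosen after the main results were seen, the median fold of a list's open promoters was set against 10000 random draws of open promoters matched on decile of GC content. Motif shares in regions listed in a single replicate were compared with shared regions of the same fold decile, and ranks by fold were compared between replicates over shared regions whose summits lay within 100 bp, with SE over 20 chromosomes. The RE1 consensus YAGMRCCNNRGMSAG was added for these tests, exact copies of the 51 bp at each summit were counted in the reference, and sequences of 25 bp were compared with the mitochondrial genome.

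Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, numba 0.67.0 and matplotlib 3.10.9, and samtools 1.23.1. Rows on scaffolds outside the chromosomes and on Y were left out of the gene and motif tests. Coordinates are 1-based in mm10.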

Results

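Open chromatin was mapped by ATAC-seq in mouse granulocyte monocyte progenitors (GMP), the committed bone marrow progenitors of neutrophils and monocytes. The series holds 1 group with 2 biological replicates, so replicate 1 against replicate 2 is the only comparison between samples. The other results describe where the open chromatin of these cells lies, and set it against random placement or against other genes. Fold enrichment is the authors' value for each region throughout. The files give no read counts, and depth is unknown.

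GMP chromatin was open at 75148 regions in the conservative series-level list, which together covered 41.2 Mb or 1.51% of the chromosomes. Their median width was 473 bp and their median fold enrichment 8.09. Replicate 1 alone gave 65423 regions over 35.2 Mb, with a median width of 471 bp and a median fold of 9.08. Replicate 2 gave 53686 regions over 28.4 Mb, with a median width of 461 bp and a median fold of 7.74. The Y chromosome, which these male cells carry, held 19 regions of the series-level list. The authors' looser lists were larger by over 1.5 times, with 116490 regions in replicate 1 and 98726 in replicate 2.

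Most accessible regions of each replicate were also found in the other. Of the regions of replicate 2, 94.2% (50558 of 53686) overlapped a region of replicate 1, against 2.695% ± 0.092 (SD, 100 placements) when placed at random. Of the regions of replicate 1, 76.7% (50194 of 65423) overlapped a region of replicate 2, against 2.21% ± 0.085 at random. For both shares p was 0.0099 (permutation test, one-sided), the smallest that 100 placements can give. With the same number of regions taken from each list, highest fold first, the shares were 80.8% and 81.8%.

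Sharing rose with fold enrichment. In replicate 1 it went from 54.7% of regions in the lowest decile of fold to 99.5% in the highest, and in replicate 2 from 79.2% to 100%. The 15229 regions in the list of replicate 1 only had a median fold of 7.30 and a median width of 327 bp, and 10.7% lay at promoters. Regions that replicate 1 shared had a median fold of 9.94, a median width of 526 bp and 26.3% at promoters. The 3128 regions in the list of replicate 2 only had a median fold of 5.61 and a median width of 296 bp, with 10.3% at promoters. In the looser list of the other replicate, 90.8% and 96.4% of these regions were present.

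**Figure D1:**
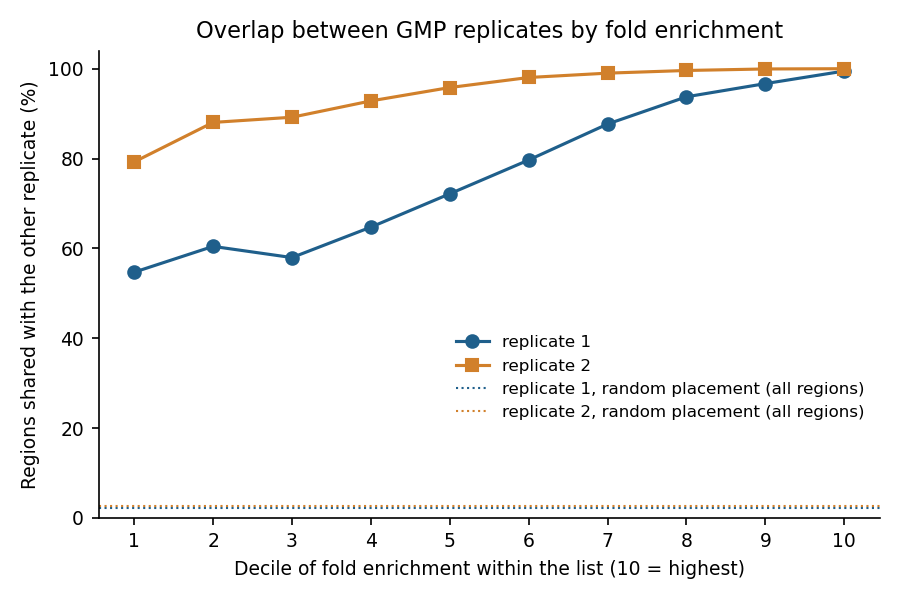
Share of regions (%) that overlap a region of the other GMP replicate by at least 1 bp, by decile of fold enrichment within each replicate's own list, with the mean of random placement of all regions as dotted lines. Replicate 1 goes from 54.7% to 99.5% and replicate 2 ends at 100%.

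Promoters were the class most enriched in open chromatin. In the series-level list 15570 summits (20.7%) lay within 1000 bp of a protein-coding TSS, 8.14 times the 2.55% ± 0.12 (SD) of random placement. Exons held 6.00% of summits against 4.30% ± 0.13, and intergenic DNA 32.5% against 52.2% ± 0.75. All of these differences had p = 0.0198 (permutation test, two-sided), the smallest possible. Introns held the largest share, 40.8%, which did not differ from the 40.9% ± 0.65 of random placement (permutation p = 0.85). Promoter shares were 22.7% in replicate 1 and 25.4% in replicate 2. The share in introns fell below random placement in each replicate alone (39.4% and 37.9%) and rose above it in the looser series-level list (43.4%) and with a promoter window of 500 bp (42.6%).

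**Figure D2:**
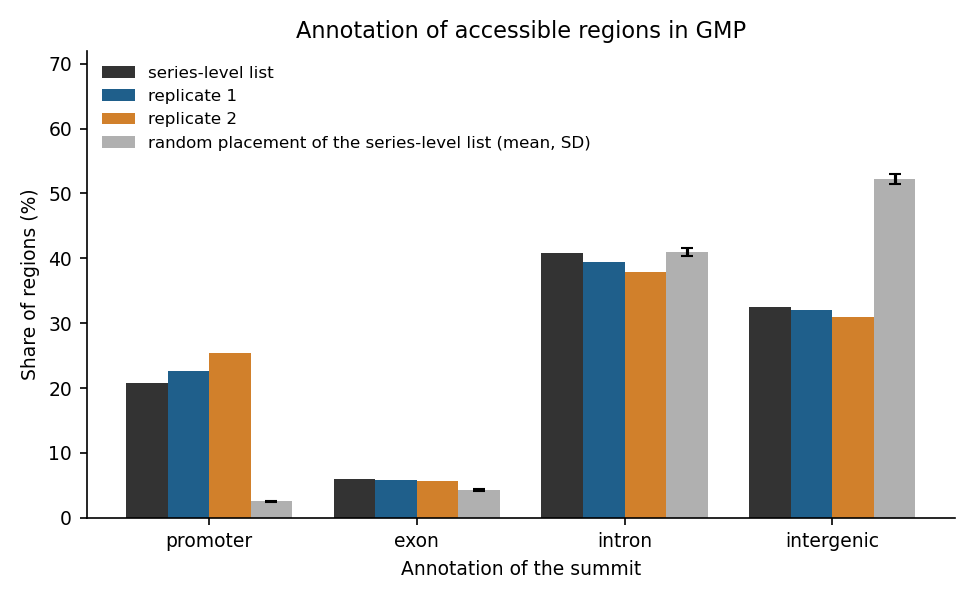
Share of regions (%) whose summit lies at a promoter, in an exon, in an intron or in intergenic DNA, for the series-level list and for each GMP replicate, beside random placement of the series-level list (mean and SD of 100 placements). Promoter bars stand at 20.7% to 25.4% against 2.55% at random.

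Promoters of the myeloid regulators and of their growth factor receptors were open without exception among the genes listed. All 16 myeloid transcription factors and all 12 myeloid cytokine receptors had a summit at a promoter, against 61.7% of other genes (adjusted p = 0.0032 and 0.015, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 18 lists, also for the values that follow). They included Spi1 (PU.1, needed for the whole myeloid lineage; fold 8.74), Cebpa (needed to form GMP, chromosome 7, 35118007 to 35119729, fold 8.46), Cebpe (granule formation; fold 5.87), Gfi1 (a repressor of the monocyte programme; fold 5.44), Irf8 (monocyte and dendritic cell fate; fold 9.77) and the receptor genes Csf3r (fold 7.48), Csf1r (fold 4.33) and Kit (fold 9.19). The call for receptors was lost in the looser list (12 of 12 open, adjusted exact p = 0.070). All 15 housekeeping genes and all 15 cell cycle genes were open as well (adjusted exact p = 0.0032 for each). Among all 21670 genes, 13382 (61.8%) had an open promoter, and 12214 (56.4%) had one in both replicates.

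Hepatocyte and muscle genes mostly lacked a promoter region in the series-level list. Of 14 hepatocyte genes 1 was open (Apob, an apolipoprotein; adjusted exact p = 0.00061), and of 13 muscle genes 2 were open (Actn2 and Ttn, sarcomere proteins; adjusted p = 0.0032). Alb and Myod1 had no promoter region. T and NK cell genes were also below other genes, with 5 of 17 open (adjusted exact p = 0.026). The open ones were Cd3d, Cd28, Thy1 (not open in replicate 2), Eomes (not open in replicate 1) and Gata3 (fold 5.16, at a region in neither replicate's list, while each replicate had another Gata3 promoter summit), while Cd3e, Cd8a, Bcl11b and Tcf7 had no promoter region in the series-level list, although Tcf7 had a region in replicate 1 alone (fold 6.70). Each of these 3 calls also held in each replicate alone. Those for muscle genes and for T and NK cell genes were lost in the looser list (adjusted exact p = 0.075 and 0.12) and among the regions with the highest fold (0.17 and 0.12).

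Effector genes of mature myeloid cells lay between. Of 12 primary granule genes 11 were open, which did not pass after adjustment (adjusted exact p = 0.083), while 12 of 12 passed with a promoter window of 2500 bp (0.029). Mpo (myeloperoxidase, chromosome 11, 87793257 to 87794253, fold 5.50), Elane (neutrophil elastase, chromosome 10, 79886096 to 79886453, fold 6.84), Ctsg (cathepsin G; fold 5.83) and Ms4a3 (a gene of the GMP stage; fold 13.9) had a promoter region in both replicates. Prtn3 (proteinase 3) had none within the promoter window. Prtn3 regions just outside it, at -1.69 kb (fold 6.73) and -2.245 kb (fold 3.93), were present in both replicates. Late neutrophil genes were open in 12 of 16 (adjusted exact p = 0.44), with Camp (an antimicrobial peptide of secondary granules) at a fold of 14.01, Ltf (lactoferrin) at 7.23, Mmp8 at 11.5 and S100a8 at 10.5. Monocyte and macrophage genes were open in 13 of 15 (adjusted exact p = 0.11).

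Promoters of other blood lineages did not differ from all other genes after adjustment in the series-level list with the 1000 bp window. Stem and multipotent progenitor genes were open in 13 of 18 (adjusted exact p = 0.60), including Cd34 (fold 8.33), Hlf (fold 7.98), Mecom (fold 5.52, at a region in neither replicate's list, while each replicate had another Mecom promoter summit) and Hoxa9 (fold 4.69). Erythroid genes were open in 8 of 15 (adjusted exact p = 0.72), with Gata1 (fold 9.99), Epor (fold 11.9), Hbb-bs (fold 16.9), Hbb-bt (fold 11.1) and Tfrc (fold 13.8) open. Klf1 and Hba-a1 had no promoter region in the series-level list (replicate 2 alone had a Klf1 promoter region at a fold of 2.80). Just outside the promoter window, Klf1 had an exonic region at 1.27 kb from its TSS (fold 12.4), present in both replicates. Megakaryocyte genes were open in 5 of 14 (adjusted exact p = 0.11), among them Itga2b (fold 4.55) and Pf4 (fold 6.41). B cell genes were open in 6 of 15 (adjusted exact p = 0.16), with Pax5 at a fold of 12.8 and Ebf1 at 11.7, and were below other genes with a promoter window of 500 bp (4 of 15, adjusted exact p = 0.033). Eosinophil, basophil and mast cell genes were open in 4 of 12 (adjusted exact p = 0.11, without Prg2), dendritic cell genes in 8 of 12 (with Siglech at a fold of 13.1), endothelial and stromal genes in 8 of 12 (with Cdh5 at 13.3) and neural genes in 9 of 15 (without Neurod1), each of the last 3 with adjusted p = 1.

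Several of these calls changed when lists were matched on promoter GC content. Against 10000 random lists matched on promoter GC, primary granule genes (91.7% open, adjusted permutation p = 0.0063) and monocyte and macrophage genes (86.7%, adjusted p = 0.0072) were above the random lists, and the transcription factors (adjusted p = 0.068), receptors (0.16), housekeeping genes (0.11) and cell cycle genes (0.068) no longer passed. Hepatocyte, muscle and T and NK cell genes stayed below (adjusted permutation p = 0.0063 for each). Megakaryocyte genes were below other genes in each replicate alone, with 3 of 14 open (adjusted p = 0.031 in replicate 2 and 0.013 in replicate 1, Fisher's exact test), and also with a promoter window of 2500 bp (5 of 14, 0.048) and among the regions with the highest fold (1 of 14, 0.030).

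Distal regions clustered around the myeloid genes. A myeloid transcription factor had a median of 14 distal regions, against 2.5 in matched random lists (adjusted p = 0.0036, permutation test with Benjamini-Hochberg adjustment over 18 lists, also below), and 287 in all over 16 genes. Id2 had 45, Runx1 (needed for blood formation and myeloid maturation) 43, Klf4 and Zeb2 34 each, Fli1 23, Gfi1 15, Irf8 13 and Cebpa 8. Monocyte and macrophage genes had a median of 7 against 2 (adjusted permutation p = 0.0094), with 38 at Ly86, 17 at F13a1 and 9 at Csf1r. Cytokine receptors had a median of 5.5 against 2 (adjusted permutation p = 0.0072), with 10 at Kit and 8 at Csf3r. Late neutrophil genes had a median of 3 against 1 (adjusted permutation p = 0.0072), and primary granule genes 2.5 against 0.5 (adjusted p = 0.042), with 4 at Mpo, 2 at Ctsg and 1 at Elane.

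B cell genes also passed, with a median of 3 against 1 (adjusted permutation p = 0.0072), of which Ebf1 held 9 and Blk 5. In replicate 2 alone and in replicate 1 alone the B cell median was 1 and the call was lost (adjusted permutation p = 0.93 and 1). The calls for monocyte genes and receptors were lost in replicate 2 alone (adjusted permutation p = 0.090 and 0.14). Their medians there were 4 and 3, against 1 for each in matched random lists. Myeloid transcription factors still passed in replicate 2 alone, with a median of 7 against 1.5 (adjusted permutation p = 0.0036). The call for primary granule genes was lost with a distal limit of 2500 bp (adjusted permutation p = 0.092).

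Outside these lists, stem and multipotent progenitor genes had a median of 5 distal regions, just short of the threshold (adjusted permutation p = 0.0504; 0.042 in the looser list and 0.045 with a distal limit of 2500 bp, but 0.15 in replicate 2 alone and 0.11 in replicate 1 alone), with 22 at Meis1, 11 at Cd34 and 12 at Mecom. Medians were 1 for erythroid and for megakaryocyte genes, 3 for T and NK cell genes (adjusted permutation p = 0.15), 1 for eosinophil, basophil and mast cell genes, 3 for dendritic cell genes (adjusted p = 0.28, but 0.035 with all regions within 50000 bp of a TSS counted, where stem and multipotent progenitor genes were at 0.38), 2 for housekeeping genes (0.15), 1 for cell cycle genes, 2 for neural genes, 0.5 for hepatocyte genes (0.48), 1 for muscle genes and 5 for endothelial and stromal genes (0.29). Those given without a p had an adjusted permutation p of 1. Over all 21670 genes the median was 1 and 37.9% had no distal region.

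**Figure D3:**
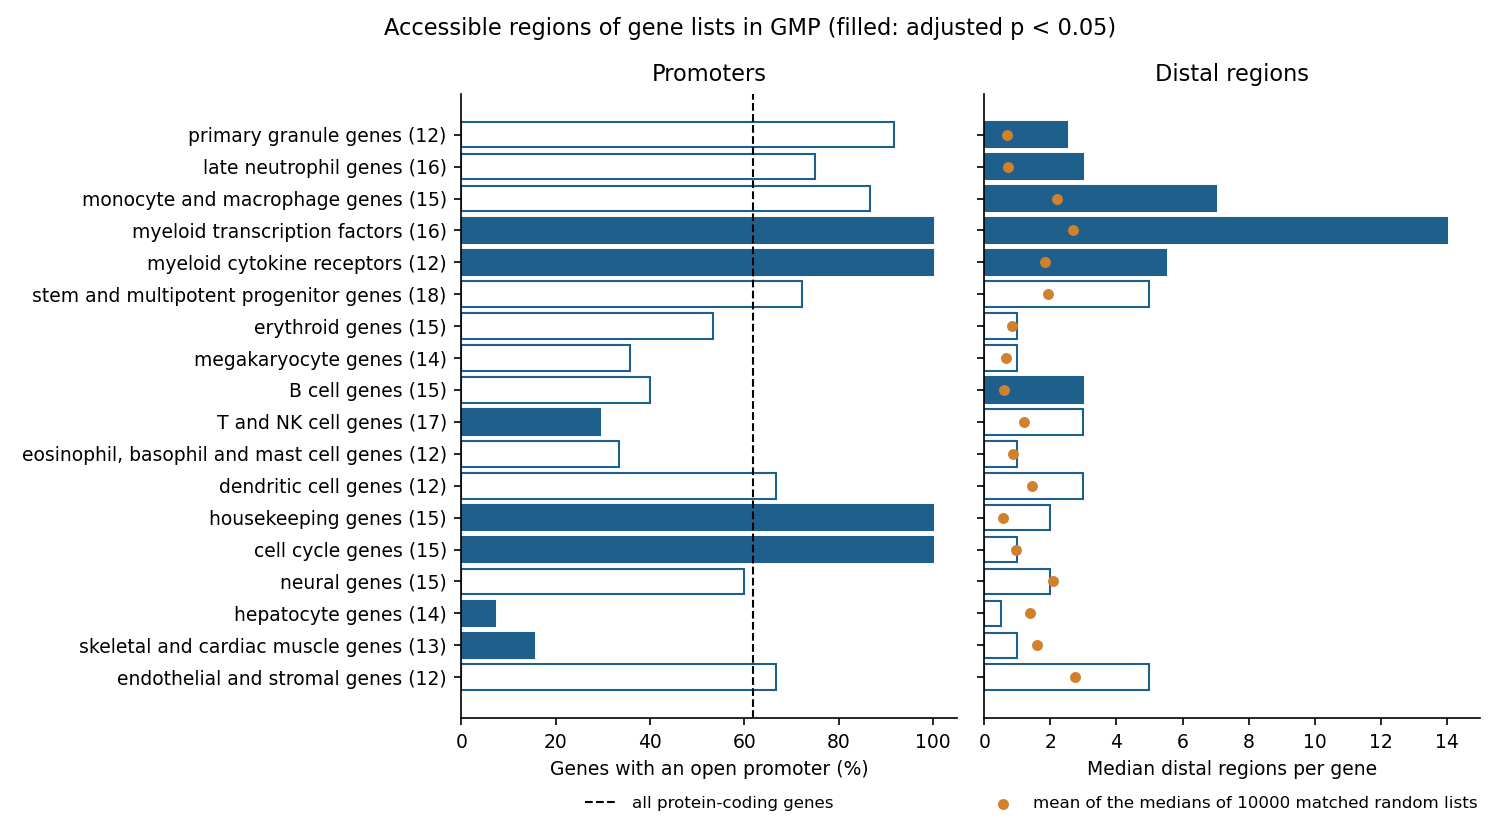
Left, share of each list's genes (%, number of genes in brackets) with a summit within 1000 bp of a TSS in the series-level GMP list, with all genes (61.8%) as a dashed line, and right, median number of distal regions per gene, with points for the mean of the medians of 10000 matched random lists. Filled bars passed the adjusted threshold, and myeloid transcription factors reach 100% and a median of 14.

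Summits far from promoters carried the binding sequences of myeloid transcription factors. At 59565 distal summits the PU.1 motif, bound by the product of Spi1, was found in 5.96% of windows against 0.467% of flanks, a log2 ratio of 3.67 ± 0.25 (SD over 20 chromosomes). The CEBP motif had a log2 ratio of 2.66 ± 0.33, with 3.86% of summits, and the RUNX motif 2.02 ± 0.25, with 4.73%. AP-1 sites followed at 1.63 ± 0.21, IRF sites at 1.40 ± 0.46 and E-boxes at 1.04 ± 0.26. The strongest enrichment was that of CTCF, the protein that anchors chromatin loops, with a log2 ratio of 6.23 ± 0.78 and 6.00% of summits. For each of these 7 motifs all 20 chromosomes had a ratio above 0.

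At promoter summits 5 motifs passed, of which CTCF and PU.1 also passed at distal summits, although PU.1 at promoters no longer passed among the regions with the highest fold (2.15). CRE sites, bound by the CREB and ATF factors, had a log2 ratio of 4.10 ± 1.10 at 15564 promoter summits, CTCF 3.83 ± 0.79, the ETS consensus 3.79 ± 0.95, KLF/SP sites 2.45 ± 0.36 (9.28% of summits) and PU.1 2.37 ± 0.94. At promoters the ratios of CEBP (1.35 ± 0.73) and RUNX (0.48 ± 1.18) did not pass 2 SD, although CEBP passed in the looser list (1.40) and against shuffled dinucleotides (2.71).

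GATA sites, bound by the factors of red cell, megakaryocyte and mast cell precursors, were not enriched. Their log2 ratio was -0.29 ± 0.15 at distal summits, below 0 on each of the 20 chromosomes but within 2 SD of 0, and -1.03 ± 0.55 at promoters. At promoters it passed 2 SD in each replicate alone, at -1.23 ± 0.56 without replicate 1 and -1.04 ± 0.48 without replicate 2. Against shuffled sequence with the same dinucleotides the GATA ratio was 0.04 ± 0.23 at distal summits and 0.007 ± 0.74 at promoters, so the lower frequency was seen only against flanks. Among the other motifs of lymphoid and liver factors, EBF1 (-0.47 ± 0.78), TCF7/LEF1 (-0.48 ± 0.33) and HNF4 (-0.16 ± 1.20) did not pass at distal summits. The SDs of EBF1 and HNF4 were wide, so only large differences could have passed. HNF1 had 0 matches at 59565 distal summits, so its enrichment could not be judged. MYB (0.56 ± 0.34), NF-kB (0.30 ± 0.35), NFI (1.54 ± 1.29), NRF1 (1.34 ± 1.05), YY1 (0.85 ± 0.75), CRE (1.85 ± 0.91), KLF/SP (1.44 ± 0.72) and ETS (2.495 ± 1.05) also missed the limit there. For the last 3, the mean over chromosomes that was held against the limit was 1.64, 1.38 and 1.94, below the ratio over all summits. The IRF ratio fell short of 2 SD in replicate 2 alone (1.41 ± 0.72) and among the regions with the highest fold (1.32 ± 0.80).

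**Figure D4:**
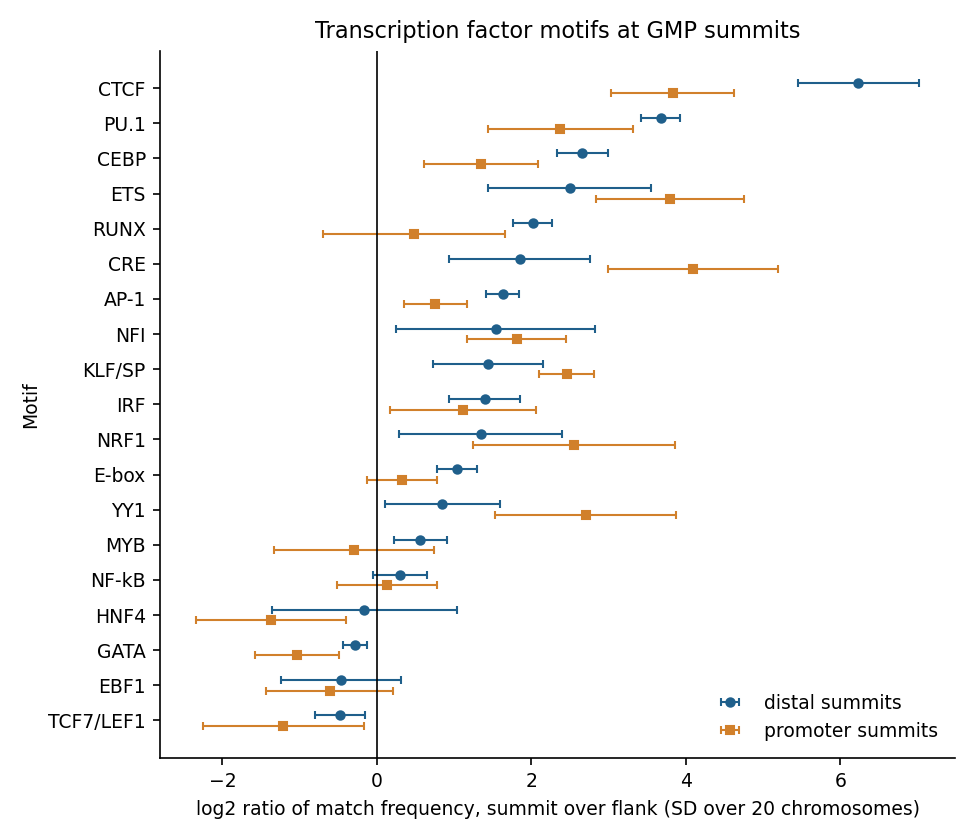
Log2 ratio of the share of summits with a motif match within 50 bp to the share in flanks 500 bp away, for distal and promoter summits of the series-level GMP list (bars, SD over 20 chromosomes). HNF1, with 0 matches, is left out, and CTCF, PU.1 and CEBP lie farthest right among distal summits.

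Of 11 positions of known blood enhancers, 10 held a region in the series-level list, while 24.4% to 30.1% of all genes had a region at the same distances. This share was not matched on the number of TSSs or of distal regions per gene. Myeloid transcription factors had many distal regions (median 14), so the contrast cannot separate these positions from other DNA near such genes. The Cebpa +37 kb enhancer, which drives Cebpa in myeloid cells, matched a region on chromosome 7 from 35156380 to 35157119 (summit at 37.4 kb, fold 6.90). For the upstream element of Spi1 (-14 kb), the region with the highest fold was intergenic, at 91069976 to 91070818 on chromosome 2 (fold 9.43). Its summit lay at -11.8 kb from 1 of the 3 annotated TSSs. A region closer to the stated distance lay at 91082845 to 91083663 (-13.7 kb, fold 5.99), itself within 1000 bp of another Spi1 TSS. This closer region was the match with a tolerance of 1000 bp and of 500 bp. Regions were also present at the Gfi1 -35 kb position (chromosome 5, 107759049 to 107759584, intron, fold 7.05), the Cebpe +6 kb position (chromosome 14, 54706453 to 54707153, intergenic, fold 7.43), the intronic Csf1r enhancer FIRE (chromosome 18, 61108121 to 61109140, fold 8.11) and the Irf8 -56 kb position (chromosome 8, 120678480 to 120678789, -57.7 kb, fold 6.48, and also 120680510 to 120680707, -55.8 kb, fold 4.67).

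Positions of stem and progenitor enhancers and an erythroid enhancer position held regions too. They were Runx1 +23 kb, Gata2 -77 kb (chromosome 6, 88116615 to 88117573, fold 9.21), Gata2 +9.5 kb (chromosome 6, 88203033 to 88203602, intron, fold 4.53) and the erythroid Tal1 +40 kb position (chromosome 4, 115095651 to 115097099, fold 6.65). For Runx1, the region with the highest fold was intronic, at 92675516 to 92676082 on chromosome 16 (21.4 kb from 1 TSS, fold 9.47). An intronic region closer to the stated distance lay at 92801537 to 92802201 (23.9 kb from another TSS, fold 8.47). This closer Runx1 region was the match with a tolerance of 1000 bp. Which of them, if either, is the described Runx1 enhancer was not tested. The upstream element of Gata1 had no region, although the Gata1 promoter did (X, 7963753 to 7964442). The Gata2 +9.5 kb region was absent from the list of each replicate alone. With a tolerance of 500 bp the Runx1 position had no region, and 9 of 11 remained.

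**Figure D5:**
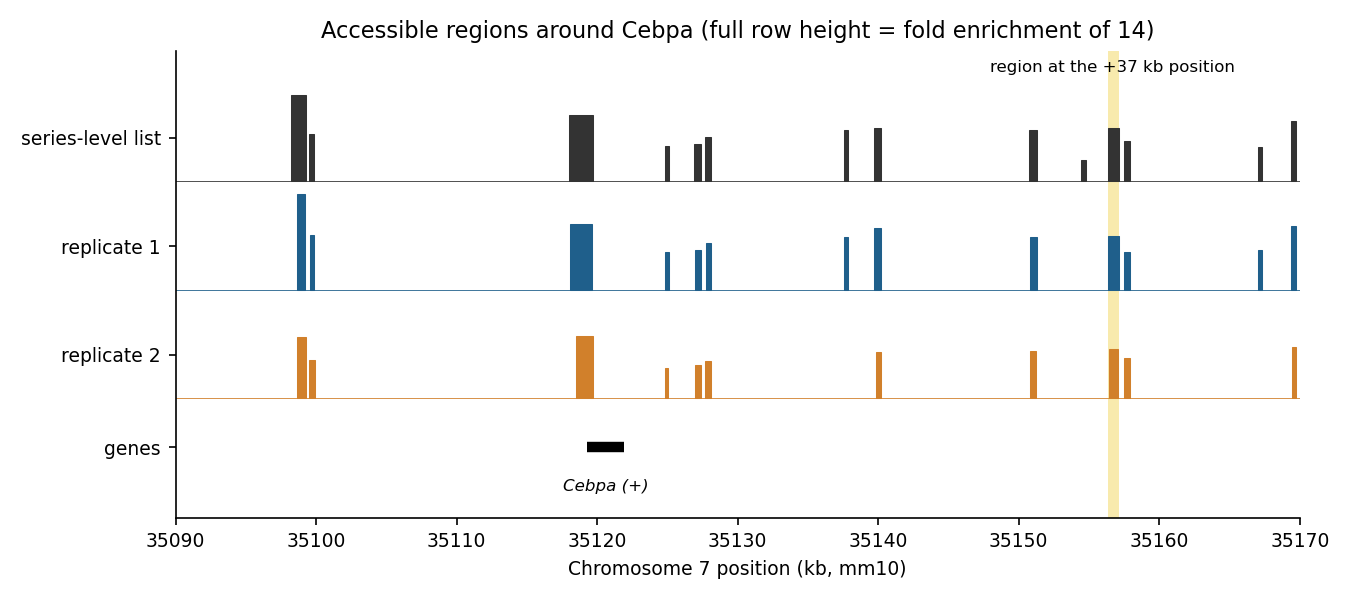
Accessible regions around Cebpa on chromosome 7 (kb, mm10) in the series-level list (14 regions), replicate 1 (13) and replicate 2 (11), where bar width is the region and bar height its fold enrichment within its own list, so heights are not compared between rows. The shaded region at the +37 kb position is present in all 3 lists.

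The strongest open regions were not at myeloid genes. Among promoters in the lists of both replicates, those of Gm5141 (chromosome 13, 62785465 to 62786165, fold 26.2), Zfp97 (chromosome 17, fold 25.5), Tstd3 (chromosome 4, fold 24.2), Gm21863 (chromosome 12, fold 23.98) and Platr25 (chromosome 13, fold 22.9) had the highest fold. The highest distal fold, 38.6, was that of an intergenic region of 257 bp on chromosome 2 from 69355474 to 69355730, at -13.0 kb from Abcb11, with 37.9 in replicate 1 and 32.7 in replicate 2. After it came an intronic region on chromosome 16 from 18533127 to 18533395, 34.4 kb from Rtl10 (fold 34.97). An intergenic region on chromosome 6 from 9889881 to 9890222 lay 940 kb from Nxph1 (fold 30.99). Another on chromosome 5, from 60042655 to 60043145, lay at -1766 kb from G6pd2 (fold 29.6). Last came an exonic region on chromosome 8 from 20424119 to 20424961, at -61.6 kb from Gm15319 (fold 29.4). These genes are those with the nearest protein-coding TSS, at whatever distance. Of the 5 promoters, 4 have a second exact copy of the 51 bp at the summit in the reference (Tstd3 does not). Of the 5 distal regions, 3 have such a copy and 3 share a sequence of 25 bp with the mitochondrial genome.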

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

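The count of intervals on scaffolds outside the assembled chromosomes was chosen after the lists had been opened, and no test was run on it. The ranked lists of GMP accessible intervals hold intervals that pass the IDR threshold but are absent from the thresholded lists used for the comparisons, and no control samples exist to set them against. In replicate 1, 50 such intervals lay on 12 scaffolds, 20 of them on chrUn_JH584304. In replicate 2, 51 lay on 14 scaffolds, 17 of them on chrUn_JH584304. The same scaffold held 31 of the 77 such intervals in the series-level ranked list. On the chromosomes, 137 intervals of replicate 1 and 143 of replicate 2 pass the threshold and are absent too. No explanation was tested for either kind.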

How the results depend on the processing

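All alternatives here were chosen before the data were examined. Of 573 recomputed values over 94 results, 483 kept their direction and their side of the threshold or stayed within the limit set for counts, 42 newly passed a threshold, 25 no longer passed, 18 moved and 5 reversed. The overlap between the replicates kept its call in 5 of 5 alternatives, in both directions.

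The looser lists gave 125024 regions for the series, 116490 for replicate 1 and 98726 for replicate 2. Introns, at random level in the series-level list, held 37.9% to 39.4% of summits without 1 replicate, 37.1% among the regions with the highest fold and 37.3% with a promoter window of 2500 bp, all below random placement. They held 43.4% in the looser list and 42.6% with a window of 500 bp, both above it.

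Among promoter lists, the looser list had 1 list below other genes, the hepatocyte genes, while muscle genes, T and NK cell genes and cytokine receptors no longer passed, and the regions with the highest fold left 1 list above, the cell cycle genes. In those regions myeloid transcription factors (31.25% open) and cytokine receptors (41.7%) turned to below other genes, without passing, and housekeeping, muscle and T and NK cell genes no longer passed. Against lists matched on GC 2 lists were above, primary granule and monocyte and macrophage genes, and the 4 lists above all other genes no longer passed. Lists with more distal regions numbered 3 to 5 without 1 replicate and 1 among the regions with the highest fold, where the B cell median was 0 and the transcription factors alone passed. The B cell call was also lost in the looser list, within 50000 bp of a TSS and beyond 2500 bp.

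At distal summits 11 motifs were enriched in the looser list and 11 with windows of 100 bp, in both cases with ETS, KLF/SP, CRE and MYB added to the 7. Distal KLF/SP also passed without replicate 1, without replicate 2 and against shuffled dinucleotides, ETS without replicate 1 and against shuffled dinucleotides, and CRE among the regions with the highest fold. At promoters AP-1 passed in the looser list, and NRF1 and YY1 with windows of 100 bp. Depleted distal motifs numbered 2 (GATA and TCF7/LEF1) among the regions with the highest fold and 1 (GATA) with windows of 100 bp. At promoters GATA was the 1 depleted motif without replicate 1, without replicate 2, in the looser list, among the regions with the highest fold and with windows of 100 bp, but not against shuffled dinucleotides (0.007 ± 0.74). Known enhancers with a region fell to 4 of 11 among the regions with the highest fold. Apart from lists that hold fewer or more regions by construction, the cause was not tested. No paired analysis was possible because the series has 1 group. Depth is unknown, so its effect on the number of regions could not be measured.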

Other observations

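The presence of replicate 1's own regions in replicate 2's looser list and the sequence of the 5 strongest distal regions were tests chosen only after the results were seen, as was matching on width, and the other tests here were chosen once the pattern they address had been noticed.

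Open promoters of several gene lists, myeloid and other, had a lower fold than open promoters of the same GC content. Among promoters with a region, the median fold was 6.46 for the 16 myeloid transcription factors, against 9.81 in random open promoters of the same GC content (adjusted permutation p = 0.0054, 18 lists). Primary granule genes (6.84 against 10.98, adjusted permutation p = 0.016), cytokine receptors (7.13 against 10.2, 0.015), stem and multipotent progenitor genes (7.33 against 10.6, 0.018) and the 5 open megakaryocyte genes (4.92 against 10.6, 0.0054) were lower too. Late neutrophil genes (7.14) and neural genes (6.14) were also lower (adjusted permutation p = 0.015 for each). Their open promoters were fewer in each replicate's own list. There the median fold was 10.1 (9 genes) and 7.11 (10 genes) for late neutrophil genes, in replicate 1 and replicate 2. For neural genes it was 8.82 (7 genes) and 9.96 (5 genes), and for megakaryocyte genes 6.43 and 5.85 (3 genes in each). Monocyte and macrophage genes (7.93 against 10.9, adjusted permutation p = 0.076) and eosinophil, basophil and mast cell genes (7.23, 0.15) did not pass. Housekeeping genes were as close to the threshold (8.003 against 10.24, adjusted permutation p = 0.076), and endothelial and stromal genes (8.102 against 10.54, 0.15) did not pass. B cell, T and NK cell and dendritic cell genes did not pass either (adjusted permutation p = 0.53, 0.27 and 0.89). The 1 open hepatocyte promoter (15.6 against 11.2) and the 2 open muscle promoters (14.1 against 10.8) lay higher, without passing. Erythroid (10.5) and cell cycle (10.98) promoters did not differ from random ones (adjusted permutation p = 0.97 and 0.70). The denominator of the fold is not given, so a lower fold need not mean less open chromatin, and its cause was not tested.

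CTCF sites differed between the replicates. In 13595 distal regions found in the list of replicate 1 only, 8.20% of summits had a CTCF motif, against 4.20% in shared regions of the same fold (log2 ratio 0.96, SE 0.065, above 0 on 20 of 20 chromosomes). With width matched as well the log2 ratio was 0.22 (SE 0.065). CEBP sites were rarer there (log2 ratio -0.42, SE 0.077), as were AP-1 sites (-0.31, SE 0.066). In the 2804 distal regions found in the list of replicate 2 only, the CTCF ratio was 0.26 (SE 0.13), and -0.31 (SE 0.13) with width matched.

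More regions stood in the list of replicate 1 only (15229) than in that of replicate 2 only (3128). Of the former 90.8% lay in replicate 2's looser list, against 3.04% ± 0.15 at random, so a difference in what passed the threshold may account for most of them. Of the latter 96.4% lay in replicate 1's looser list, so these shares do not tell why the 2 counts differ. Over 36133 distal regions of both lists, those with CTCF sites stood 8.30 percentile points higher by fold in replicate 1, relative to regions without (SE 0.43; 6.28, SE 0.59, with width and mean rank matched), while CEBP sites stood lower (-2.37, SE 0.28), which is consistent with stronger recovery of CTCF sites in replicate 1. Erythroid or megakaryocytic cells in replicate 1 stay open. The log2 ratio of GATA sites in its own regions was 0.12 (SE 0.098), within the limit of 2 SE set for it. With width matched it was 0.24 (SE 0.10), beyond 2 SE. In rank by fold over the shared distal regions, those with GATA sites stood at -0.39 percentile points (SE 0.32) in replicate 1, within 2 SE. The labels list 2 instruments for replicate 1 and none for replicate 2, depth is unknown, and no biological explanation beyond such cells was tested, as the series has 1 group.

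The 100 regions with the highest fold (21.7 to 38.6), all in both replicates' lists, lay mostly in introns (38) and intergenic DNA (46). Copies of mitochondrial DNA were found in 4 of them (4%), against 22 of all regions (0.029%). They were thus more frequent here, but too few to account for the group. Only exact matches of 25 bp were counted, so diverged copies would be missed. CTCF sites lay under 2% of the summits (5.01% of all regions), which argues against CTCF sites as the source of the group. A sequence present in more than 1 copy in the reference genome was found under 18 summits, against 2 of 100 random regions, too few to account for the group and too many to set aside. The nearest genes of the 5 strongest distal regions were Abcb11, Rtl10, Nxph1, G6pd2 and Gm15319, some of them far away. Mitochondrial or second nuclear copies were present in 5 of these 5 regions, so reads from other copies may raise their fold. The other 78 of the 100 had none of these 3 features, and no biological explanation beyond CTCF binding was tested.

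Promoters of the neural genes Syn1 (synapsin; X, 20920787 to 20921299, fold 17.5) and Snap25 (a synaptic membrane protein; chromosome 2, 136714029 to 136714480, fold 19.97) had the highest fold of the 9 open neural promoters, in the series-level list and in both replicates. An RE1 site, the site of the repressor REST, lay under the summit of 1 of them, Snap25, and also at the weaker promoters of Gad2 (fold 6.14) and Grin1 (fold 12.2), so whether it bears on the fold could not be decided. Over all promoter summits, the 69 with an RE1 site had a median fold percentile of 58.5 against 59.8 for the others (permutation p = 0.85). Both lay above 98.7% of open promoters of the same GC decile (99.6% for Syn1), so most open promoters of similar GC content had a lower fold. The 2 were picked for their high fold, so this rank cannot decide whether GC content contributes. No biological explanation beyond the RE1 site was tested.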
